A study of Mus musculus with 12 samples.

How the data were processed

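RNA was measured in 12 mouse kidney libraries, 4 in each of 3 groups, taken from the titles in the labels. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was selected by its poly(A) tail, and strand-marked libraries made with dUTP were sequenced as read pairs on a NovaSeq X Plus. The submitters' processing notes name fastp, StringTie, edgeR and the mouse genome build GRCm39. Their versions, the aligner and the gene annotation are not given in the sources used here. The deposited files give, per the file headers, a count and an FPKM value (fragments scaled by gene length and library total) for each of 32047 genes in each library. The FPKM values the authors deposited were checked against the counts over 1245 genes with an FPKM above 20 in every library. There the gene length they imply varied between libraries with a median coefficient of variation of 0.497%. The FPKM values were not used further. A gene annotation supplied for the re-analysis, separate from the deposited files, paired 31942 gene identifiers with a symbol and left 105 without one. The genome supplied with the data is of another build, so gene names were used and no coordinates are given.

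The deposited counts summed to 55324078 to 70638283 per library. Among low values a count of 4 occurred 11995 times, against 5847 for 3 and 3638 for 5. A count of 8 occurred 5627 times, against 3434 for 7 and 2377 for 9. Single events may thus have been counted more than once, and counts are not taken as independent molecules. The cause was not tested. Floors and folds against groups at 0 use a nominal 3 counts per library. Since a single event may give more counts than that, these floors may not cover counting error in full. They cover no other error. Library pairs within groups differed by chi-square per degree of freedom of 34.1 to 148, so no library was counted as a duplicate.

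The comparisons were AKI_mcherry against NC, AKI_FGF23_R176QR179Q against AKI_mcherry and AKI_FGF23_R176QR179Q against NC. Each was fitted on its own 8 libraries with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3. TMM factors computed over all 12 libraries were 1.12 to 1.15 in the FGF23 variant group, 0.903 to 1.02 in AKI_mcherry and 0.879 to 0.911 in NC. CPM values use these factors, and each gene test used factors computed anew on its own 8 libraries. Gene lists numbered 36, with 495 members, of which 493 were found in the files, 4 by an older symbol. Lists were tested two-sided with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 36 lists, and again with an estimated correlation and with fry. A list score per library is the mean over members of log2(CPM + 1), each centred and divided by its SD over the 12 libraries. Scores were compared by an exact two-sided permutation test over 70 assignments. The groups, tests, gene lists, naming rule and alternatives were chosen before the data were examined, except where the text says otherwise.

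Named genes follow a rule. In each comparison they are the 6 genes with the largest rise and the 6 with the largest fall by log2 fold change, among those past the threshold whose groups did not overlap and whose mean was at least 5 CPM, leaving out symbols made of Gm and digits or ending in Rik. To these are added up to 3 members of each list that passed camera and up to 1 in each direction from the others, printed from the lists with the smallest p. The genes Fgf23, Kl, Fgfr1, Cyp27b1, Cyp24a1, Slc34a1, Slc34a3, Havcr1, Lcn2, Hmox1, Krt20 and Egr1 are always named. For the FGF23 variant group against NC, list members were not named.

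To set both effects against each other, unchanged libraries were simulated 20 times. All 12 libraries were drawn from the means of AKI_mcherry and the dispersions of the fit of the FGF23 variant group against AKI_mcherry. This gave a median SD of log2 CPM of 0.200 in AKI_mcherry, against 0.199 in the deposited libraries. The AKI_mcherry libraries were also split 2 and 2 in 6 arrangements. The simulation was rebuilt in this form only after the output of a first version was seen, which had kept the deposited AKI_mcherry libraries and so cancelled their shared error by construction. The alternatives were RLE factors, upper quartile factors, library totals alone, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom with quality weights, all 12 libraries in 1 fit, the replicate number as a block, an added log2 fold change of at least 1, and leaving out each library in turn. The gene test was tested on simulated data with 200 changed genes. For changes of 1.5-fold, 2-fold and 4-fold it recovered 14.1%, 56.1% and 84.1% of genes for AKI_mcherry against NC (3 false calls), 3.03%, 56.5% and 78.1% for the FGF23 variant group against AKI_mcherry (6 false calls), and 43.3%, 53.8% and 82.5% for the FGF23 variant group against NC (7 false calls). Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.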

Results

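Kidney RNA sequencing covered 12 mouse libraries in 3 groups of 4. FGF23 is a hormone made by bone that lowers renal phosphate reabsorption and active vitamin D. The series overexpressed a form of it with the substitutions R176Q and R179Q, and produced acute kidney injury by rhabdomyolysis, the breakdown of skeletal muscle, 3 weeks afterwards. One group is labelled NC, which the labels do not expand. The AKI_mcherry group carries the name of mCherry, a red fluorescent protein, and the AKI_FGF23_R176QR179Q group, called the FGF23 variant group here, that of the hormone variant. Library totals were 61591826, 62541124, 68292668 and 70638283 counts in NC, 57347520, 55324078, 61811832 and 65730739 in AKI_mcherry, and 69124036, 69271791, 62589499 and 61687187 in the FGF23 variant group. The labels do not say whether the libraries of a group came from separate animals, nor on which day kidneys were collected, so p-values measure the spread between these samples. No uninjured group with the FGF23 variant was analysed here, so its effect could be compared after injury only. No group labelled as mCherry without injury was analysed either, so AKI_mcherry differs from NC by injury and by whatever else the groups received, and changes called with injury below are the difference between these groups.

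Fgf23 (ENSMUSG00000000182), the overexpressed gene, had 320 to 517 counts in each library of the FGF23 variant group, a mean of 5.92 ± 1.15 CPM (counts scaled to the library total and its TMM factor, SD, n = 4). It had 0 counts in all 8 other libraries. Against a nominal floor of 3 counts per library, Fgf23 was 98.6-fold higher than in AKI_mcherry and 107-fold higher than in NC. These folds are not lower bounds, since 1 event may give more than 3 counts. The labels do not give the sequence of the overexpressed gene, and reads from a construct with other codons would not be counted. The first principal component of the 500 most variable genes held 76.4% of the variance and placed NC at 40.7 to 45.2, the FGF23 variant group at -19.2 to -1.36 and AKI_mcherry at -34.0 to -28.5. The second held 13.3% and placed the FGF23 variant group at 14.6 to 22.3, NC at -5.91 to -4.09 and AKI_mcherry at -15.38 to -12.03. Within groups, log2 CPM of library pairs correlated at 0.989 to 0.996 across genes, which are not independent replicates.

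**Figure D1:**
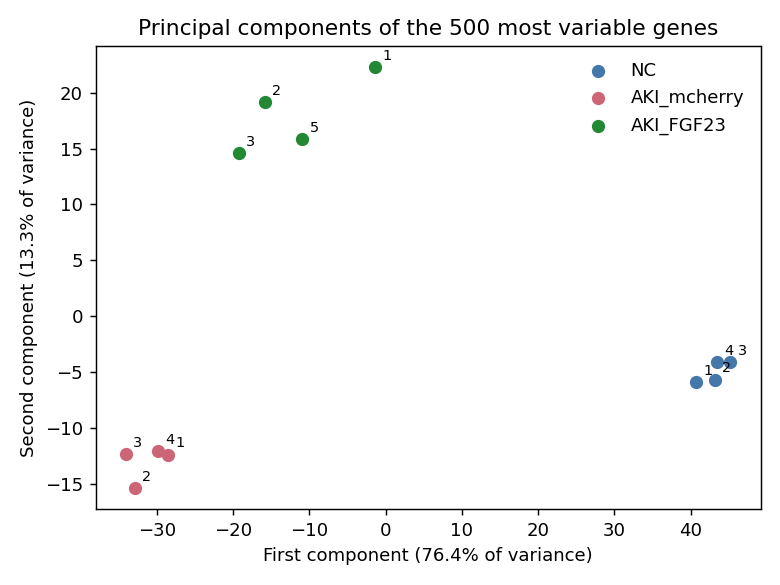
Principal components of the 500 most variable genes, with the percent of variance on each axis. Each point is a library, coloured by group and numbered by replicate (AKI_FGF23 stands for the FGF23 variant group), and the FGF23 variant group lies between NC and AKI_mcherry on the first axis.

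The comparison of AKI_mcherry with NC asked how expression in the injured kidney differed from that in NC. Havcr1, which encodes the injury molecule KIM-1, rose from 3.26 ± 1.23 to 2812 ± 746 CPM (SD, n = 4 each), a log2 fold change of 9.77 ± 0.39 (SE, edgeR quasi-likelihood test, adjusted p = 5.16e-08). Lcn2, encoding the secreted injury marker NGAL, rose 492-fold, Krt20, a keratin of injured tubules, 287-fold, and Hmox1, the heme-degrading enzyme, 21.3-fold. Kl, the FGF23 co-receptor klotho, fell from 849.5 ± 180.4 to 110.2 ± 15.2 CPM (log2 -2.92 ± 0.18, adjusted p = 4.54e-07). The sodium-phosphate cotransporter genes Slc34a1 and Slc34a3 were 13.3-fold and 14.6-fold lower. Of 18724 genes tested, 5088 were higher and 4859 lower in AKI_mcherry.

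Egr1, an immediate early transcription factor, rose 7.81-fold (edgeR adjusted p = 4.30e-04), and Fgfr1, a receptor that binds FGF23 together with klotho, rose 1.26-fold (adjusted p = 0.0111). The vitamin D genes did not pass the test: Cyp27b1, the 1-alpha-hydroxylase, was at 8.04 ± 6.92 against 5.48 ± 1.56 CPM (adjusted p = 0.465), and Cyp24a1, the 24-hydroxylase, at 59.7 ± 30.0 against 64.7 ± 24.8 CPM (adjusted p = 0.854). Fgf23 was not detectable in either group at this depth. Sprr2f, of the cornified envelope, and Fosl1, of the AP-1 transcription factors, had 0 counts in NC. Against the nominal floor of 3 counts per library they were 869.5-fold and 463-fold higher. Vgf, a secreted neuropeptide precursor, rose to 98.4 ± 32.8 CPM, and the fucosyltransferase gene Fut2 to 14.4 ± 6.90 CPM, each with counts in 1 NC library. Sprr2f belongs to a family of similar genes, and counting could split reads between them. The largest falls by the naming rule were in A4gnt (188-fold), Pde6a (101-fold), Egf (93.9-fold), Pvalb (92.8-fold), Car14 (87.5-fold) and Prok1 (78.9-fold). In AKI_mcherry, A4gnt was at 0.0945 ± 0.116 CPM, Pde6a at 0.169 ± 0.161, Pvalb at 0.160 ± 0.128 and Prok1 at 0.173 ± 0.0840. These folds rest on low counts and are imprecise. The libraries of the groups did not overlap for 51.5% of tested genes, against 2.86% by chance.

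Genes of 4 nephron segment lists fell, and tubular injury genes rose in 19 of 20 (19 higher and 0 lower adjusted over the list alone). All 25 measured genes of proximal tubule segments S1 and S2 fell (0 higher and 25 lower adjusted over the list alone), with a median log2 change of -2.81. G6pc, of gluconeogenesis, was 66.8-fold lower and Gatm, of creatine synthesis, 25.0-fold lower. All 11 genes of segment S3 fell (0 higher and 11 lower adjusted over the list alone), among them the transporters Slc7a13 (51.2-fold) and Slc22a30 (11.5-fold), the latter with near copies. In the thick ascending limb 10 of 11 fell (0 higher and 10 lower adjusted over the list alone), including Slc12a1, the furosemide-sensitive cotransporter, at 94.5 ± 13.1 against 1307 ± 280.2 CPM. In the distal convoluted and connecting tubule 9 of 11 fell (0 higher and 9 lower adjusted over the list alone). By camera with a preset correlation the adjusted p was 3.14e-39 for tubular injury, 2.35e-22 for S1 and S2, 6.82e-12 for S3, 2.60e-08 for the thick ascending limb and 3.16e-04 for the distal list. Tubular injury held (adjusted p = 0.00791 with an estimated correlation), and the segment lists did not (adjusted p = 0.0708 with an estimated correlation for S1 and S2, 0.0834 for S3, 0.0674 for the thick ascending limb and 0.224 for the distal list).

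Stress and inflammatory lists rose by camera. NRF2 targets, of the antioxidant response, had 9 higher and 1 lower of 14 (9 higher and 1 lower adjusted over the list alone), and p53 targets 12 higher and 1 lower of 16 (12 higher and 1 lower adjusted over the list alone). Both lists held (adjusted p = 0.0310 with an estimated correlation for NRF2 and 0.0310 for p53). All 11 immediate early and heat shock genes rose (11 higher and 0 lower adjusted over the list alone), Atf3, a stress-induced transcription factor, by 47.3-fold (adjusted p = 0.0908 with an estimated correlation). Cytokine, chemokine and adhesion genes had 15 higher of 19 (15 higher and 0 lower adjusted over the list alone, adjusted p = 0.0908 with an estimated correlation). FGF receptor and ERK response genes had 12 higher and 3 lower of 17 (12 higher and 3 lower adjusted over the list alone, adjusted p = 0.0674 with an estimated correlation). The unfolded protein and integrated stress response had 11 higher and 2 lower of 15 (11 higher and 2 lower adjusted over the list alone, adjusted p = 0.161 with an estimated correlation). Heme and iron handling had 9 higher and 2 lower of 17 (10 higher and 2 lower adjusted over the list alone, adjusted p = 0.0674 with an estimated correlation). Fibroblast and matrix genes had 10 higher and 1 lower of 16 (11 higher and 2 lower adjusted over the list alone, adjusted p = 0.544 with an estimated correlation), cell cycle genes 15 higher of 24 (16 higher and 0 lower adjusted over the list alone, adjusted p = 0.558 with an estimated correlation) and ferroptosis genes 5 higher and 1 lower of 11 (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.142 with an estimated correlation).

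Fatty acid oxidation genes had 1 higher and 19 lower of 21 (1 higher and 19 lower adjusted over the list alone, adjusted p = 0.184 with an estimated correlation), with the peroxisomal enzyme gene Ehhadh 9.02-fold and the fatty acid hydroxylase gene Cyp4a10 6.54-fold lower. Nuclear-encoded oxidative phosphorylation genes had 15 lower of 20 (0 higher and 15 lower adjusted over the list alone, adjusted p = 0.267 with an estimated correlation) and renin-angiotensin genes 5 lower of 7 (0 higher and 6 lower adjusted over the list alone, adjusted p = 0.142 with an estimated correlation). The mineral handling list, with Kl and both phosphate transporters, had 3 higher and 10 lower of 17 (3 higher and 10 lower adjusted over the list alone, adjusted p = 0.224 with an estimated correlation). In all, 19 of 36 lists passed camera with the preset correlation, 11 up and 8 down, and 3 held with an estimated one. The other 17 did not pass (camera adjusted p 0.0516 to 0.738): collecting duct, podocyte, endothelium, macrophage and monocyte, neutrophil, lymphocyte, mitochondrially encoded, interferon, hypoxia and glycolysis, complement, red blood cell, skeletal muscle, liver, fat, adrenal, urothelium and sex genes. Of these, neutrophil, hypoxia and glycolysis, liver and sex genes passed by list scores, which give each library 1 value (exact permutation test, adjusted p = 0.0447 each). Scaled by library totals alone, 5828 genes were higher and 3958 lower, with the median of all genes at 0.12 in place of -0.00264 on the log2 scale.

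The comparison of the FGF23 variant group with AKI_mcherry asked what the overexpressed variant changed in the injured kidney. Cyp24a1, which degrades active vitamin D, rose from 59.7 ± 30.0 to 579 ± 201 CPM (SD, n = 4 each), a log2 change of 3.28 ± 0.39 (SE, edgeR adjusted p = 7.96e-04). Cyp27b1, which makes it, fell from 8.04 ± 6.92 to 0.799 ± 0.449 CPM (log2 -3.33 ± 0.75, adjusted p = 0.0125). The injury genes were lower, Havcr1 2.68-fold (adjusted p = 0.0146), Lcn2 4.49-fold (0.00988), Hmox1 3.29-fold (8.68e-04), Krt20 3.18-fold (0.00958) and Egr1 2.17-fold (0.0149). Kl was 2.24-fold higher (adjusted p = 0.00463). Of 18824 genes tested, 2199 were higher and 2148 lower. Scaled by library totals alone the split was 4060 higher and 1035 lower, with the median of all genes at 0.21 in place of 0.00837 on the log2 scale.

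The phosphate transporter genes did not pass the test, with Slc34a1 at 486 ± 238 against 345 ± 19.2 CPM (edgeR adjusted p = 0.218) and Slc34a3 at 6.65 ± 4.17 against 3.06 ± 1.93 CPM (0.126). Fgfr1 was at 61.4 ± 4.68 against 74.1 ± 5.41 CPM (edgeR adjusted p = 0.0585) and passed with DESeq2 (adjusted p = 0.0311, 0.0311 to 0.643 over the alternatives). The largest rises by the naming rule were in Ugt1a2 (405-fold), Slc7a12 (289-fold), Ugt1a1 (72.2-fold), Prlr (25.1-fold), Nccrp1 (22.6-fold) and Ccl28 (17.7-fold). Slc7a12 was at 0.0990 ± 0.0746 CPM in AKI_mcherry, so its fold rests on low counts. Ugt1a1 and Ugt1a2, UDP-glucuronosyltransferases, share exons with other Ugt1a genes, so the split of reads between them is uncertain. The prolactin receptor gene Prlr reached 51.7 ± 16.8 against 2.06 ± 0.725 CPM. The largest falls were in Slco1a1 (127-fold), Sprr2f (50.6-fold), Ctxn3 (46.7-fold), Krt14 (37.8-fold), Pzp (23.9-fold) and Vgf (21.8-fold), of which Slco1a1 encodes an organic anion transporter and Krt14 a keratin of basal epithelium. Slco1a1 was at 0.314 ± 0.391 CPM in the FGF23 variant group, so its fold rests on low counts too. The libraries of the groups did not overlap for 28.4% of tested genes, against 2.86% by chance.

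**Figure D2:**
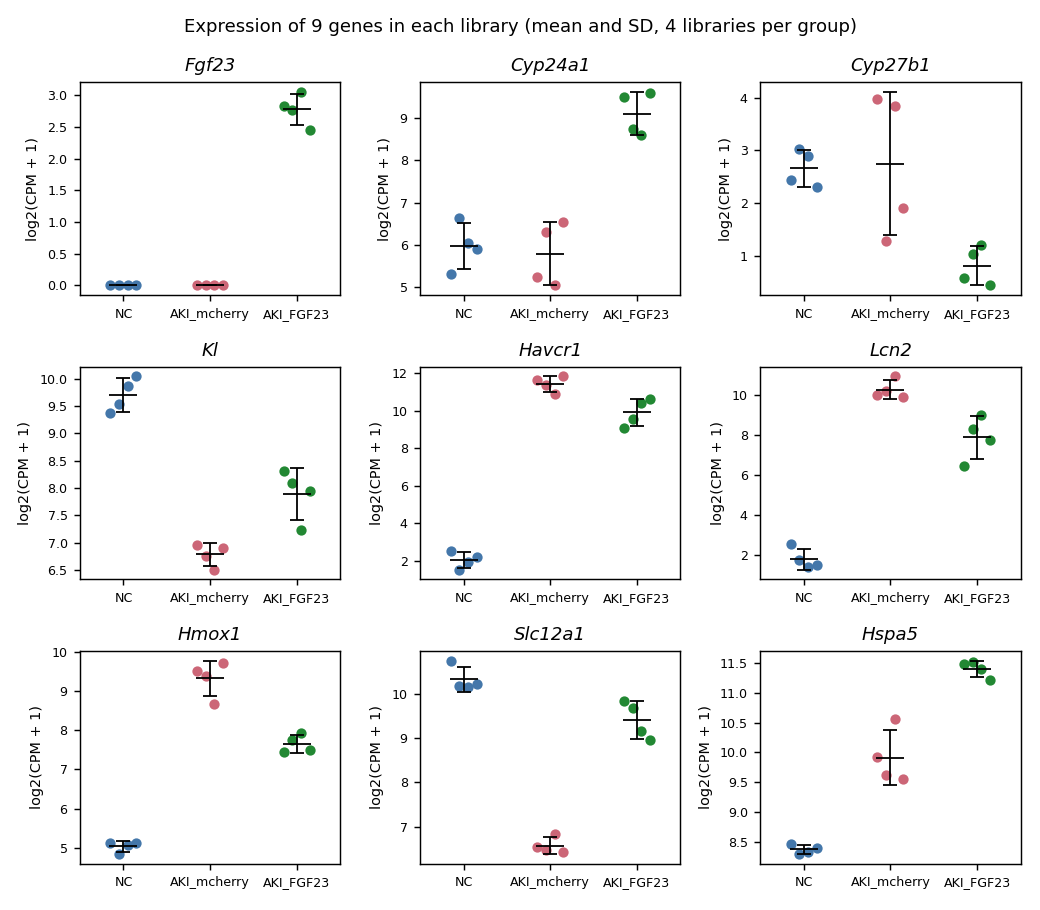
log2(CPM + 1) of 9 genes in each library, by group (AKI_FGF23 stands for the FGF23 variant group), with the mean and SD of 4 libraries; each panel has its own axis. Fgf23 is at 0 outside the FGF23 variant group, Cyp24a1 is highest there, and Havcr1, Lcn2 and Hmox1 lie between NC and AKI_mcherry.

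In the thick ascending limb 10 of 11 genes were higher in the FGF23 variant group than in AKI_mcherry (10 higher and 0 lower adjusted over the list alone, adjusted p = 0.182 with an estimated correlation), Slc12a1 from 94.5 ± 13.1 to 700.2 ± 199 CPM and Egf, the epidermal growth factor gene, by 14.2-fold. The distal convoluted and connecting tubule had 7 higher and 1 lower of 11 (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.495 with an estimated correlation). Segments S1 and S2 of the proximal tubule had 13 higher and 2 lower of 25 (15 higher and 2 lower adjusted over the list alone, adjusted p = 0.502 with an estimated correlation), with G6pc 10.3-fold higher. Segment S3 did not pass (camera adjusted p = 0.330), with 4 higher and 1 lower of 11 (4 higher and 2 lower adjusted over the list alone). Renin-angiotensin genes had 4 higher of 7 (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.380 with an estimated correlation) and endothelial genes 5 higher of 12 (6 higher and 0 lower adjusted over the list alone, adjusted p = 0.546 with an estimated correlation).

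Tubular injury genes fell in 16 of 20 (0 higher and 16 lower adjusted over the list alone, adjusted p = 0.182 with an estimated correlation), Plin2, which encodes a lipid droplet coat protein, by 7.54-fold and the keratin gene Krt19 by 7.08-fold. The unfolded protein and integrated stress response had 9 higher of 15 (12 higher and 0 lower adjusted over the list alone, adjusted p = 0.182 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, reached 2719 ± 250.0 against 1003 ± 351 CPM, and Pdia4, a disulfide isomerase, was 3.13-fold higher. Mitochondrially encoded genes fell in 11 of 13 (0 higher and 11 lower adjusted over the list alone, adjusted p = 0.495 with an estimated correlation). Genes with the symbol prefix mt-, which may be more than these 13, took 10.9% to 13.1% of counts in the FGF23 variant group. They took 13.8% to 17.1% in AKI_mcherry. Nuclear copies make the reads of single members uncertain. Cell cycle genes had 5 lower of 24 (0 higher and 7 lower adjusted over the list alone, adjusted p = 0.580 with an estimated correlation) and immediate early genes 5 lower of 11 (0 higher and 5 lower adjusted over the list alone, adjusted p = 0.575 with an estimated correlation). Neither of these lists passed by directional fry (adjusted p = 0.0631 and 0.0777). The liver marker list passed upward with 3 higher and 2 lower of 7 (3 higher and 2 lower adjusted over the list alone, adjusted p = 0.502 with an estimated correlation), a mean log2 change of 0.76 and a median of -0.11, which became 0.0949 when scaled by library totals alone.

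In all, 11 of 36 lists passed camera with the preset correlation, 7 up and 4 down, and 0 held with an estimated one. List scores put the thick ascending limb at 0.43 ± 0.41 against -1.10 ± 0.16 and tubular injury at 0.25 ± 0.22 against 0.93 ± 0.08 (SD, n = 4 each). By the exact two-sided permutation test of these scores, 9 of 36 lists reached 0.0286, the smallest p that 70 assignments allow, and 0 passed after Benjamini-Hochberg adjustment (lowest 0.114). The other 25 lists had camera adjusted p of 0.0685 to 0.971. They were S3, collecting duct, podocyte, macrophage and monocyte, neutrophil, lymphocyte, fibroblast and matrix, cytokines, heme and iron, NRF2, ferroptosis, p53, fatty acid oxidation, oxidative phosphorylation, mineral handling, ERK response, interferon, hypoxia, complement, red blood cell, skeletal muscle, fat, adrenal, urothelium and sex genes. Fat markers stood apart in AKI_mcherry replicate 3, with a score of 1.77 against -0.963 to -0.542 in the other 3 libraries, and skeletal muscle and urothelium scores were highest there too, at 1.65 against -0.385 to 0.593 and 1.76 against -0.539 to 0.414.

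Without FGF23 variant group replicate 1, 1252 genes were higher and 1158 lower, without replicate 2, 1494 and 1359, without replicate 5, 1439 and 1279, and without replicate 1 and AKI_mcherry replicate 3 together, 1120 and 1006. That last fit, though not it alone, ended the call of Cyp27b1 (edgeR adjusted p = 0.0699, 5.36e-04 to 0.0760 over the alternatives). A fit of all 12 libraries ended those of Krt20 (0.0559, 3.87e-06 to 0.0559 over the alternatives) and Egr1 (0.0823, 1.94e-04 to 0.0823 over the alternatives). Of 86 named genes, the fit without both libraries ended the calls of 12, the replicate block 12 and the fit of all 12 libraries 4.

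**Figure D3:**
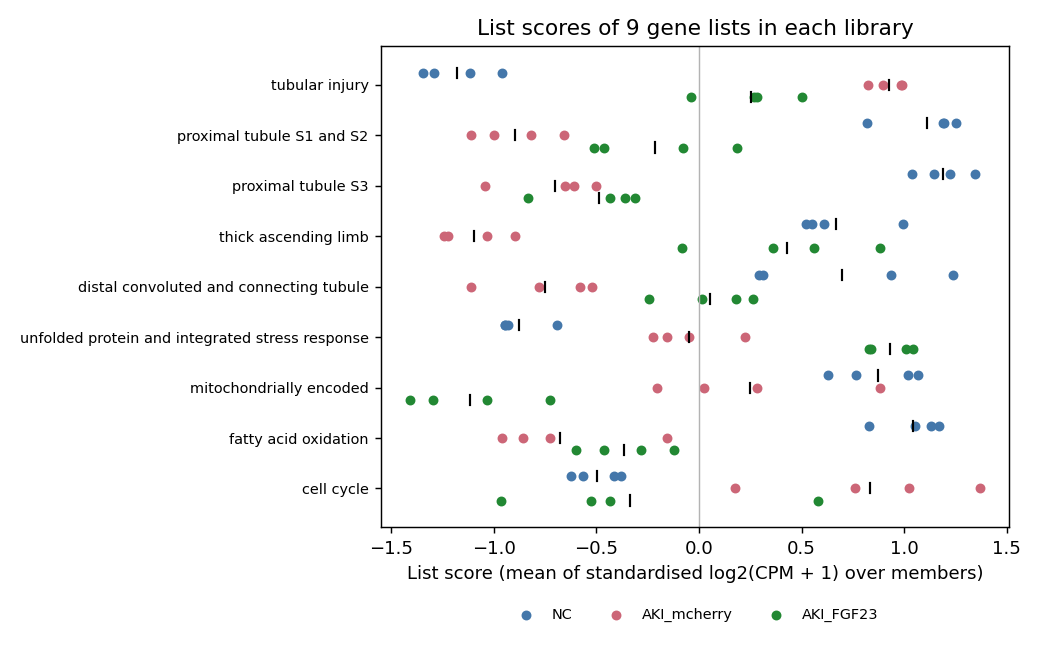
Scores of 9 gene lists in each library, where a score is the mean over members of log2(CPM + 1), each centred and divided by its SD over 12 libraries. Points are libraries, bars are group means, and AKI_FGF23 stands for the FGF23 variant group, whose thick ascending limb scores lie at -0.0852 to 0.884 against -1.24 to -0.896 in AKI_mcherry and 0.523 to 0.993 in NC.

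The effects of injury and of the FGF23 variant were set against each other over the 18282 genes tested in both comparisons. Genes that rose with injury and fell in the FGF23 variant group numbered 1738, and 1628 fell and then rose, which makes 3366 in opposite directions. These were 34.5% of the genes changed with injury. Another 193 changed in the same direction in both. Independent lists of these sizes would share 598 genes of the first kind, 547 of the second and 1145 in the same direction. All 10 thick ascending limb genes that fell with injury rose in the FGF23 variant group, as did 13 of 25 genes of S1 and S2 (2 fell further), 4 of 11 of S3 (1 fell further) and 5 of 19 of fatty acid oxidation (3 fell further). Of 5 mitochondrially encoded genes that fell with injury, 3 fell further and 0 rose (edgeR). Of 19 tubular injury genes that rose with injury, 16 fell, of 15 cytokine genes 4 fell and 3 rose further, and of 9 NRF2 targets 2 fell and 3 rose further. Of 11 unfolded protein response genes that rose with injury, 0 fell and 6 rose further (edgeR). Slco1a1, Acsm3 and Pzp fell in both comparisons.

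Both comparisons share the AKI_mcherry libraries, which sets their log2 changes against each other by chance. Across genes the log2 changes correlated at r = -0.663, and 20 simulations of unchanged libraries gave a mean of -0.511. The covariance was -0.730 against a simulated -0.0585, a difference of -0.672. With the AKI_mcherry libraries split 2 and 2 between the comparisons, the covariance was -0.871 to -0.811 over 6 arrangements, r was -0.522 to -0.467, and 1346 to 2734 genes were opposite, 15.4% to 31.0% of those changed with injury. The split fits were filtered anew and kept 19098 to 19192 genes, against 18282 without a split. Their covariance is thus over another set of genes, and its size is not compared with -0.730. Genes are not independent replicates, and the simulation drew each gene separately. Without FGF23 variant group replicate 1, 1901 genes were opposite, and without replicate 5, 2174.

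**Figure D4:**
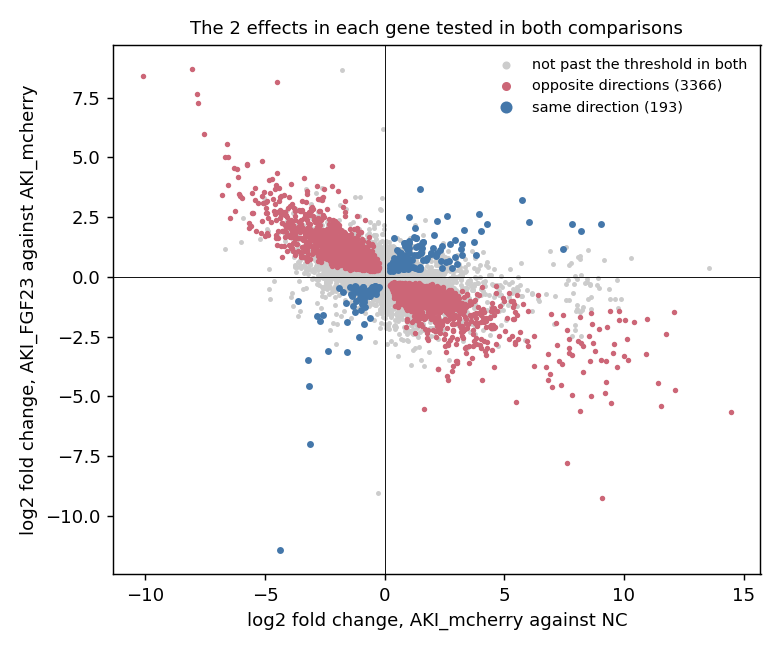
log2 fold change of each gene in AKI_mcherry against NC (horizontal) and in the FGF23 variant group against AKI_mcherry (vertical). Coloured points passed the threshold in both comparisons, 3366 in opposite directions and 193 in the same direction, and the shared AKI_mcherry libraries tilt the cloud even with no effect.

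The comparison of the FGF23 variant group with NC asked how far the injured kidney with the variant lay from the NC kidney. Havcr1 was 326-fold higher than in NC (log2 8.35 ± 0.47, SE, n = 4 each, edgeR adjusted p = 8.34e-07), Lcn2 109-fold, Krt20 90.3-fold, Hmox1 6.44-fold and Egr1 3.59-fold. Kl was 3.40-fold lower (adjusted p = 1.41e-04), Slc34a1 9.46-fold and Slc34a3 6.71-fold. Cyp24a1 was 9.08-fold higher (adjusted p = 3.02e-05) and Cyp27b1 6.78-fold lower (adjusted p = 3.38e-04). Fgfr1, at 61.4 ± 4.68 against 59.5 ± 3.87 CPM, did not pass (edgeR adjusted p = 0.573), and did when scaled by library totals alone (0.00200, 0.00200 to 0.817 over the alternatives). Of 19005 genes tested, 4123 were higher and 3912 lower. By library totals alone the split was 7829 higher and 2096 lower, with the median of all genes at 0.34 in place of 0.0109 on the log2 scale.

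Fosl1 had 0 counts in NC and was 596-fold higher against the nominal floor of 3 counts per library. The other large rises by the naming rule were in the metalloproteinase gene Mmp10 (15.2 ± 9.29 CPM, with counts in 1 NC library), the cystine transporter gene Slc7a11 (392-fold), Ugt1a9 (21.5 ± 18.7 CPM, edgeR adjusted p = 6.07e-04) and Ptprn (187-fold). Ugt1a9 shares exons with its family and did not pass with limma-voom (adjusted p = 0.150, 6.00e-05 to 0.150 over the alternatives). The largest falls were in Slco1a1 (1119-fold), Pzp (218-fold), Acsm3 (102-fold), Inmt (52.6-fold), Pde6a (45.4-fold) and Dpys (40.8-fold). Slco1a1 was at 0.314 ± 0.391 CPM in the FGF23 variant group and Slc7a11 at 0.156 ± 0.0896 CPM in NC, so their folds rest on low counts. The unfolded protein response had 13 higher of 15 (13 higher and 0 lower adjusted over the list alone, adjusted p = 0.0169 with an estimated correlation). Cytokines had 15 higher of 18 (16 higher and 0 lower adjusted over the list alone, adjusted p = 0.0169 with an estimated correlation), p53 targets 11 higher of 16 (11 higher and 0 lower adjusted over the list alone, adjusted p = 0.0172 with an estimated correlation) and NRF2 targets 11 higher and 2 lower of 14 (11 higher and 2 lower adjusted over the list alone, adjusted p = 0.0334 with an estimated correlation). ERK response genes had 13 higher and 2 lower of 17 (14 higher and 2 lower adjusted over the list alone, adjusted p = 0.0334 with an estimated correlation), and heme and iron genes 10 higher and 2 lower of 17 (10 higher and 2 lower adjusted over the list alone, adjusted p = 0.0488 with an estimated correlation).

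A further 12 lists passed with the preset correlation alone. Tubular injury had 18 higher of 20 (19 higher and 0 lower adjusted over the list alone, adjusted p = 0.0565 with an estimated correlation), immediate early genes 10 higher of 11 (11 higher and 0 lower adjusted over the list alone, adjusted p = 0.128 with an estimated correlation), fibroblast and matrix genes 10 higher of 16 (11 higher and 1 lower adjusted over the list alone, adjusted p = 0.146 with an estimated correlation) and ferroptosis genes 6 higher and 2 lower of 12 (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.0527 with an estimated correlation). Segments S1 and S2 had 1 higher and 23 lower of 25 (1 higher and 23 lower adjusted over the list alone, adjusted p = 0.177 with an estimated correlation) and S3 10 lower of 11 (0 higher and 10 lower adjusted over the list alone, adjusted p = 0.0565 with an estimated correlation). Fatty acid oxidation had 18 lower of 22 (0 higher and 18 lower adjusted over the list alone, adjusted p = 0.0565 with an estimated correlation), nuclear-encoded oxidative phosphorylation 20 lower of 20 (0 higher and 20 lower adjusted over the list alone, adjusted p = 0.177 with an estimated correlation) and mitochondrially encoded genes 13 lower of 13 (0 higher and 13 lower adjusted over the list alone, adjusted p = 0.160 with an estimated correlation). The distal convoluted and connecting tubule had 1 higher and 6 lower of 11 (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.392 with an estimated correlation), renin-angiotensin genes 4 lower of 7 (0 higher and 4 lower adjusted over the list alone, adjusted p = 0.0945 with an estimated correlation) and mineral handling 4 higher and 10 lower of 18 (5 higher and 12 lower adjusted over the list alone, adjusted p = 0.338 with an estimated correlation). The thick ascending limb did not pass (camera adjusted p = 0.172), with 4 lower of 11 (0 higher and 4 lower adjusted over the list alone), though it did by directional fry (0.0321). The other 17 lists did not pass camera either (adjusted p up to 0.865), and of these the lymphocyte, neutrophil, hypoxia and glycolysis, and complement lists passed by list scores (adjusted p = 0.0468 each).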

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

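In 19 of 273 groups of 4 values, 1 library stood further from the others than Dixon's criterion allows, and chance gives about 1 in 20 such groups. Of these, 10 lay in NC, 6 in AKI_mcherry and 3 in the FGF23 variant group. Among those in NC, Vgf, Fut2, Mmp10 and Ugt1a9 were at 0 in 3 of 4 libraries, which meets the criterion by construction. The rate of 1 in 20 does not hold for them, and the count in NC is raised by that. The fit without AKI_mcherry replicate 3 and FGF23 variant group replicate 1 together was chosen only after the result was seen. No explanation was weighed for these values. The score of proximal tubule S1 and S2 transport and metabolism was 0.819 in NC replicate 1, against 1.19 to 1.25 in the other 3. The score of unfolded protein and integrated stress response was -0.690 in NC replicate 2, against -0.948 to -0.932 in the other 3. The score of p53 targets and apoptosis was 0.259 in AKI_mcherry replicate 2, against 0.621 to 0.664 in the other 3. The score of fat markers was 1.77 in AKI_mcherry replicate 3, against -0.963 to -0.542 in the other 3.

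Genes are given as log2(CPM + 1). Vgf was at 0.20 in NC replicate 1, against 0 in the other 3. Fut2 was at 0.19 in NC replicate 2, against 0 in the other 3. Slc22a30 was at 8.43 in NC replicate 3, against 8.12 to 8.17 in the other 3. Cyp4a10 was at 9.16 in NC replicate 1, against 8.81 to 8.86 in the other 3. Slc12a1 was at 10.75 in NC replicate 1, against 10.16 to 10.23 in the other 3. Nccrp1 was at 5.89 in NC replicate 1, against 4.56 to 4.77 in the other 3. Mmp10 was at 0.0979 in NC replicate 2, against 0 in the other 3. Ugt1a9 was at 0.41 in NC replicate 3, against 0 in the other 3. Cyp4a10 was at 7.19 in AKI_mcherry replicate 1, against 5.58 to 5.74 in the other 3. Pzp was at 2.98 in AKI_mcherry replicate 3, against 4.08 to 4.14 in the other 3. Krt19 was at 7.12 in AKI_mcherry replicate 3, against 5.77 to 5.93 in the other 3. Acsm3 was at 6.25 in AKI_mcherry replicate 3, against 7.48 to 7.69 in the other 3. Slc34a3 was at 3.80 in FGF23 variant group replicate 1, against 2.45 to 2.51 in the other 3. Slc7a12 was at 5.79 in FGF23 variant group replicate 1, against 4.48 to 4.63 in the other 3. Ugt1a1 was at 4.43 in FGF23 variant group replicate 5, against 5.26 to 5.39 in the other 3.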

How the results depend on the processing

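The fit without AKI_mcherry replicate 3 and FGF23 variant group replicate 1 together was chosen only after the result was seen. Named genes kept their direction and side of the threshold under the alternatives they were tested in, the log2 threshold not being among them and the mean of at least 5 CPM leaving 74, 71 and 21 of them, in 78 of 85 for AKI_mcherry against NC, 64 of 86 for the FGF23 variant group against AKI_mcherry and 21 of 23 for the FGF23 variant group against NC. Lists were rerun only with RLE factors, an estimated correlation, fry, the replicate block and 1 library left out, and kept theirs in 8 of 36, 7 of 36 and 12 of 36. In that order, a log2 fold change of at least 1 left 2444 higher and 2609 lower, 854 higher and 576 lower, and 1371 higher and 1511 lower, by construction. Library totals alone gave 5828 higher and 3958 lower, 4060 higher and 1035 lower, and 7829 higher and 2096 lower. Without both doubted libraries the counts were 4836 higher and 4643 lower, 1120 higher and 1006 lower and 3983 higher and 3858 lower. Leaving out 1 library at a time, in the same order, gave 4643 to 5000 higher and 4273 to 4799 lower, 1252 to 2088 and 1158 to 2171, and 3540 to 4167 and 3437 to 3881, with 19 to 20, 11 to 14 and 18 to 21 lists past the threshold. Lists past it numbered 19, 11 and 18, with an estimated correlation 3, 0 and 6, by directional fry 28, 13 and 25, and by the mixed test of fry, which ignores direction, 30, 27 and 30. List scores past it numbered 23, 0 and 22, with medians 24, 0 and 21, and over members of at least 5 CPM 21, 0 and 20. Genes in opposite directions numbered 1079 with a log2 fold change of at least 1, 1756, 1512, 2106, 1346, 2734 and 1730 over the split arrangements, where each comparison had fewer AKI_mcherry libraries, and 1901 to 3349 leaving out 1 library. The first principal component held 66.0% over all genes. Cyp24a1 in AKI_mcherry against NC, which did not pass, changed sign to 0.013 by library totals alone, 0.090 without AKI_mcherry replicate 1, 0.13 without replicate 3 and without both doubted libraries, and 0.18 without NC replicate 2, and ranged from -0.38 to 0.18 leaving out 1 library (log2). Apart from the log2 threshold and the smaller fits, the cause was not tested.

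The replicate numbers were not treated as pairs. Deviations of same-numbered libraries correlated across genes at -0.288 to 0.0836, 0.0819 to 0.190 and -0.169 to -0.0818 in the 3 comparisons. Libraries of different number correlated at -0.191 to 0.227, -0.240 to 0.281 and -0.300 to 0.262. So few pairs cannot show whether the samples were paired. The replicate block gave 4370 higher and 4250 lower, 984 higher and 803 lower, and 2388 higher and 2335 lower. The FGF23 variant group is numbered 1, 2, 3 and 5, so only 3 numbers matched in each comparison with it. Libraries without a match add nothing to the group effect in a block fit, so these lower counts also reflect fewer libraries. With 8 libraries a 1.5-fold change was recovered in 3.03% of simulated genes for the FGF23 variant group against AKI_mcherry. Few genes were changed in that simulation, which makes the adjusted threshold stricter than in the deposited libraries. There 4347 genes passed, and 1430 of them had an absolute log2 fold change of at least 1, so most calls were of smaller changes. The share of small changes missed in the deposited libraries was not measured. Pseudocounts planned for data without counts were not run.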

Other observations

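The tests of library scaling, of a return towards NC, of female or mixed-sex animals, of fewer proximal tubule cells, of fewer S3 cells and of a general male to female shift were chosen only after the result was seen. With injury, 6 of 7 neutrophil genes rose (6 higher and 0 lower adjusted over the list alone) and macrophage and monocyte genes had 6 higher and 2 lower of 16 (6 higher and 2 lower adjusted over the list alone), and neither list passed camera (adjusted p = 0.0516 and 0.116). By list scores the neutrophil list passed (adjusted p = 0.0447) and the macrophage and monocyte list did not (0.248), and by directional fry both did (0.00289 and 0.0382). In the FGF23 variant group against AKI_mcherry, complement and acute phase genes had 6 higher and 1 lower of 15 (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.117, 0.171 by list scores and 0.0394 by directional fry), and all 6 of them that fell with injury rose. Interferon response genes had 4 higher and 1 lower of 17 (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.298).

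Of 20 genes known to differ between male and female mouse kidney, 11 changed in the FGF23 variant group against AKI_mcherry. These genes were chosen after most of their values were seen. With injury, 13 of 14 male-typical and 5 of 6 female-typical genes were lower than in NC. The female-typical Hao2, a peroxisomal oxidase, was at 232 ± 90.9 against 15.8 ± 2.05 CPM (SD, n = 4 each, edgeR adjusted p = 4.70e-05). Its log2 change with injury was -3.89, and the FGF23 variant group lay at log2 -0.0205 ± 0.23 (SE) from NC. Rdh16f2, a retinol dehydrogenase, was at 139 ± 29.3 against 10.8 ± 2.27 CPM (adjusted p = 1.45e-05). The male-typical Kap, an androgen-regulated kidney protein, was at 1701 ± 543 against 9861 ± 4291 CPM (adjusted p = 0.00128) and Cyp4a12a, with a near copy, at 5.72 ± 5.48 against 50.7 ± 29.6 CPM (adjusted p = 0.00920). The male-typical Slc7a13 rose, to 88.4 ± 44.3 against 18.4 ± 4.89 CPM, and the female-typical Cyp2a4 fell, to 175 ± 28.7 against 333 ± 118 CPM.

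Over all 35 splits of 8 libraries into 4 and 4, 1 split, the real one, reached 9947 changed genes for AKI_mcherry against NC, with 0 in the highest other split (edgeR, 10927 and 2210 at an unadjusted p under 0.05). For the FGF23 variant group against AKI_mcherry the real split gave 4347 and the highest other 0 (7060 and 3132 unadjusted), and for the FGF23 variant group against NC 8035 and 1 (9424 and 2644 unadjusted). In each comparison the real split ranked highest, which chance alone gives in 1 of 35 cases, the lowest rate this test can reach. The other splits mix the groups, which widens their spread, so adjusted counts near 0 there do not measure chance.

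Of the genes changed with injury, 34.5% changed in the opposite direction in the FGF23 variant group, past the threshold in both comparisons, and the others did not. Shared AKI_mcherry libraries alone would leave no negative covariance when each comparison has its own AKI_mcherry libraries, and it was -0.811 at its highest over 6 arrangements. A single milder library does not account for it either, since without FGF23 variant group replicate 1, 15 of 20 tubular injury genes were still lower, though the share in the opposite direction came to 19.5% with fewer libraries. The pattern may be a milder injury or a faster recovery with the FGF23 variant, a hypothesis found and tested on the same data. The files cannot separate these, since the labels give no measure of the muscle damage and no day of collection.

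Of 15 unfolded protein response genes, 9 were higher in the FGF23 variant group than in AKI_mcherry, and the list passed camera with the preset correlation but not with an estimated one (adjusted p = 0.182). Library scaling is argued against by a list median 0.88 above that of all genes on the log2 scale, and a return towards NC by a median of 0.70 among the 11 members that rose with injury (6 rose again, 0 fell). Of 2 members that fell with injury, 2 rose, which a return would also give. Of 20 further endoplasmic reticulum folding genes, listed before their values were seen, 15 (75%) were higher and 0 lower, among them the chaperone Hsp90b1 at 1758 ± 159 against 654 ± 162 CPM (edgeR adjusted p = 8.11e-04). These 20 genes were compared with AKI_mcherry only, so a return towards NC was not tested for them. A candidate explanation is a broad folding response of the secretory pathway. Whether the hormone's action or the load of making an overexpressed secreted protein would raise it stays open, because both go with the group.

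Female or mixed-sex animals are argued against by 4 Y-linked genes, whose lowest ratio of FGF23 variant group to AKI_mcherry was 1.04, with Xist at 0.0595 to 0.600 CPM over all libraries. The 24 S1 and S2 genes outside the 20 sex-biased ones had a median log2 change of 0.93 (13 higher, 1 lower). As a set they did not share the fall of the male-typical genes. They had fallen with injury, and transcript levels do not count cells, so fewer proximal tubule cells could not be judged. The 7 S3 genes outside those 20 had a median of 0.0968 (SD 0.71), with 3 higher and 0 lower by edgeR. The smallest fall of a male-typical gene that passed was -2.40, so these 7 genes did not share that fall. Whether any of the 7 also differ between the sexes was not checked, so fewer cells of segment S3 could not be judged either. The S3 list as a whole did not pass camera (adjusted p = 0.330). A return towards NC is argued against for most of the changed genes, since 9 of 11 sex-biased ones differed from NC in the direction of their change, with 3 of 4 risen female-typical genes above NC and 5 of 5 fallen male-typical genes below it. For Hao2 and Slc7a13 a return stays open. Of 20 sex-biased genes 11 changed, 9 of them (81.8%) in the female-typical direction. Most of this list was written after its genes were noted in these data, and of the 9 genes not noted before, 2 changed and 0 in that direction, so a general shift cannot be told apart from a choice of genes. An effect of the FGF23 variant itself stays open, since it goes with the group.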
